A study of Mus musculus with 24 samples.

How the data were processed

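Ribosome-associated RNA was measured in 24 spinal cord pulldowns from mice of 8 weeks. In the RiboTag method, Cre recombinase switches on an epitope-tagged copy of the ribosomal protein Rpl22, and an antibody against the tag pulls down ribosomes with their mRNA. Cre was driven here from the choline acetyltransferase (ChAT) locus, which is active in cholinergic cells such as motor neurons. The labels gave 4 groups of 6 mice: heterozygous Gars C201R or wild type, each with Cre or without it. Pulldowns without Cre served as the background measured in the same way. Each library came from a mouse with its own number, and samples are named here by that number.

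The deposited files held expected counts per gene, estimated with RSEM 1.2.12 after alignment with Bowtie2 2.2.0, per the submitters' processing notes. The genome build and annotation were not given in the sources used here, so no coordinates are printed. Each file listed 38924 genes with symbols. Of their identifiers, 37607 matched the GENCODE gene names at hand, which were used to update 3 symbols. Expected counts need not be whole and were rounded to whole numbers. Reads shared between near-identical genes, such as ribosomal protein genes and their pseudogenes, had been divided by RSEM, so their values are uncertain. The library numbers in the descriptions fell into 2 separate runs, called library series 1 (7 libraries) and library series 2 (17 libraries); the labels do not say what the runs stand for. No pair of libraries agreed closely enough to be taken as one library deposited more than once.

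Each comparison of a pair of groups was fitted on its own 12 libraries, and the interaction and the pooled enrichment on all 24. Genes were filtered with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (R 4.3.3) by the robust quasi-likelihood F test, with library series as a term. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called. Standard errors (SE) are the log2 fold change divided by the square root of F. CPM, the count divided by the scaled library total, is scaled within the fit of the comparison it stands beside. The plot of single genes, the account of single outlying libraries, the levels of lists per library, the exact tests of single genes, and the ratios and floors over few counts use a scaling over all 24 libraries. A group with a total of 0 counts was given a floor of 3 counts over the group, and ratios over few counts have exact 95% binomial intervals. Both cover counting error only and leave out the spread between mice. Because PCR copies are not independent molecules, they may understate counting error as well.

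The 28 gene lists, the comparisons, the rule for named genes and most alternatives were fixed before the data were examined. List tests in the interaction were not among those fixed. Lists were tested with camera (limma 3.58.1, preset correlation 0.01, two-sided, adjusted over the lists with at least 3 measured members), again with an estimated correlation, and with fry. Named genes are the 12 higher and 12 lower called genes with the smallest p and a mean of at least 2 CPM (for enrichment, the largest changes), without predicted genes, small RNAs, pseudogenes, Xist, Tsix and Y-linked genes; Gars, Rpl22 and Chat; and from each list up to 4 called members, or else the 2 most abundant. Library measures were compared by exact two-sided permutation tests, adjusted over 20 tests, and again with labels exchanged only within library series, a test added after the data were seen. Bootstrap intervals of list medians take the members as independent. Alternatives were RLE scaling, DESeq2 1.42.0, limma-voom with quality weights, other filters, other covariates, subsets of libraries and leaving out each library in turn. The labels did not give the sex of the mice, so Xist was used as a covariate in an alternative fit. Another took the mouse number prefix as a replicate block. There, libraries whose prefix holds only 1 genotype carry no information on the genotype change. Among libraries with Cre these are prefix 14003 (C201R only) and prefixes 14002 and 14702 (wild type only).

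The tests were tested on simulated data. For the genotype comparison with Cre, counts were drawn for 14470 genes with 200 changed. edgeR recovered 35% of the genes changed 2-fold and 69% of those changed 4-fold, and 3.7% of its calls were wrong. DESeq2 recovered 56% and 82%, with 18.3% of its calls wrong. Camera called all 3 shifted lists of 30 and 0 of the others. The simulated genes were drawn independently, whereas estimated correlations in the real lists of this comparison reached 0.646 (blood cell markers). The simulation therefore does not test camera on lists of correlated genes.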

Results

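The study asked how a dominant Gars mutation changes the ribosome-associated mRNA of motor neurons in adult mice. Gars encodes glycyl-tRNA synthetase, which charges tRNA with glycine, and dominant mutations in it cause a hereditary neuropathy of peripheral axons. Each of the 4 groups had 6 libraries. Totals ranged from 8.9 to 28.3 M expected counts. The means were 18.3 ± 3.3 M (SD, n = 6) in C201R with Cre, 21.5 ± 4.7 M in wild type with Cre, 11.3 ± 2.4 M in C201R without Cre and 12.5 ± 1.7 M in wild type without Cre.

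Library composition differed with Cre. Mitochondrial transcripts took 45.4 ± 5.4% of counts in C201R and 48.3 ± 4.7% in wild type without Cre, and 6.9 ± 4.5% and 5.0 ± 6.0% with Cre (SD, n = 6; exact two-sided permutation p = 0.0022 in each genotype, the smallest the design allows, and 0.0048 adjusted over 20 tests; within library series, adjusted p = 0.0099 in each genotype). Most of the mitochondrial share came from the mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2. Together they took 38.3 ± 5.1% of counts in C201R and 41.8 ± 6.8% in wild type without Cre, and 6.0 ± 4.1% and 4.3 ± 5.4% with Cre. Gm26924, a gene model that collects ribosomal RNA reads, took 25.4 ± 14.5% of counts in C201R with Cre and 13.2 ± 8.8% in wild type with Cre, with an exact two-sided permutation p of 0.10 (adjusted p = 0.17) over all splits. With labels exchanged only within library series the exact permutation p was 0.031 (adjusted p = 0.052). Within series 1 the means were 37.7% in 3 C201R libraries and 21.4% in 2 wild-type libraries, and within series 2 they were 13.1% in 3 and 9.2% in 4. The highest share of each group with Cre was 43.3% in C201R mouse 14003-1 and 30.8% in wild-type mouse 14701-9.

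**Figure D1:**
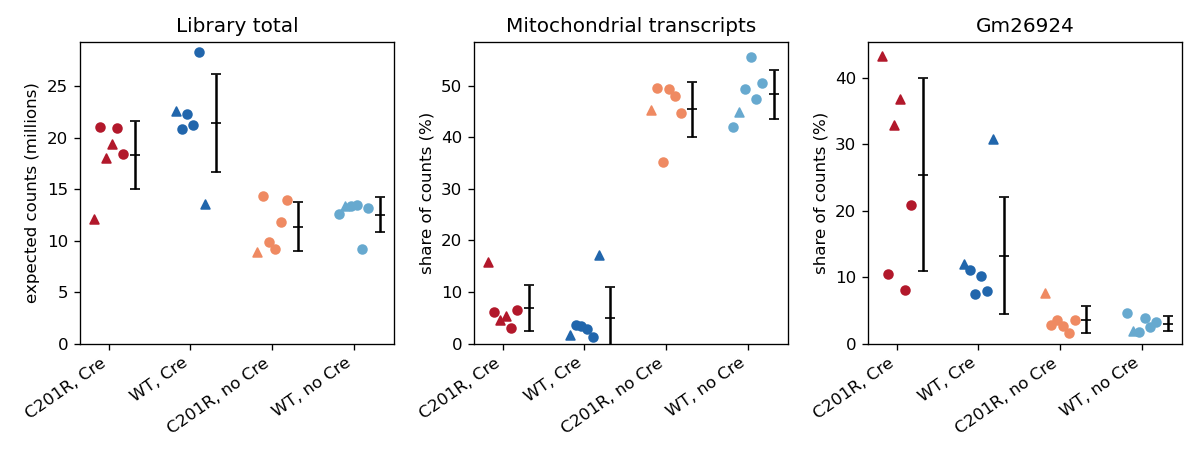
Totals in Ms of expected counts (left) and shares of counts in percent taken by mitochondrial transcripts (middle) and Gm26924 (right), one point per library, with triangles for library series 1, circles for series 2 and bars for mean and SD of 6 libraries. Mitochondrial shares lie between 35.2% and 55.5% without Cre and between 1.2% and 17.1% with Cre.

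Pulldowns with Cre were enriched for cholinergic transcripts and depleted of glial ones. Over both genotypes, all 16 measured cholinergic and motor neuron markers were higher with Cre, with a median log2 change of 3.37 (camera adjusted p with an estimated correlation, 0.014). Chat itself was higher by 4.44 ± 0.25 on the log2 scale (SE, adjusted p = 8.9e-15), the choline transporter Slc5a7 by 3.83 ± 0.20 and the motor neuron gene Chodl by 4.69 ± 0.28. The neuropeptide genes Uts2b and Calcb, the transcription factor Mnx1 and the vesicle protein gene Slc10a4 were among the largest changes. All 12 oligodendrocyte markers were lower, with a median of -3.26, as were 11 of 12 astrocyte markers (median -2.89) and all 13 microglia markers (median -2.83). The astrocyte glutamate transporter Slc1a2 had a log2 change of -3.52 ± 0.15. The oligodendrocyte and astrocyte lists kept their call with an estimated correlation (adjusted p = 0.0073 and 0.012), and the microglia list did not (adjusted p = 0.11).

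Of 16109 genes tested in the pooled comparison, 5374 were higher and 6027 lower with Cre. In wild type alone 3955 of 14264 genes were higher and 4682 lower, and Chat was higher by 3.59 ± 0.32 (adjusted p = 1.9e-07). In C201R alone 4370 of 14335 genes were higher and 3775 lower, and Chat was higher by 5.09 ± 0.34 (adjusted p = 6.2e-09). The interaction test did not call Chat (1.47 ± 0.45, adjusted p = 0.26). These splits depend on scaling. With library totals alone, an alternative chosen after seeing the data, 6881 genes were higher and 2441 lower for Cre enrichment in wild type, 5657 and 2284 for Cre enrichment in C201R, and 7421 and 3865 for pooled Cre enrichment. The median of all genes moved from -0.12 to 0.55 in the pooled comparison.

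In pulldowns with Cre, C201R mice had higher levels of the targets of ATF4, the transcription factor of the integrated stress response. Of 39 measured list members, 26 were higher, 0 were lower and 13 did not pass the test. Adjusted over the list alone, 34 were higher. The median log2 change was 1.33, and it was 1.33 as well with the member at 0 counts placed at its bound. Fgf21, a secreted metabolic hormone, stood at 49.5 ± 26.7 CPM in C201R and at 0.066 ± 0.076 CPM in wild type (SD, n = 6), and the ratio of the summed counts, 4241 over 10 scaled over all 24 libraries, was 604 with a counting interval of 328 to 1260. The secreted peptide gene Adm2 had 0 counts in wild type and was at least 318-fold higher. Nupr1, a stress-induced transcriptional regulator, was higher by 5.05 ± 0.28 on the log2 scale (SE, adjusted p = 8.9e-08). The serine synthesis genes Psat1, Psph and Phgdh were higher by 2.48 ± 0.12, 2.55 ± 0.20 and 3.08. Atf4 itself was higher by 1.67 (adjusted p = 9.4e-05). For Psat1, Fgf21 and Nupr1 all 6 C201R libraries lay above all 6 wild-type ones. The list was called by camera (adjusted p = 7.9e-80) and with an estimated correlation (adjusted p = 2.5e-06).

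**Figure D2:**
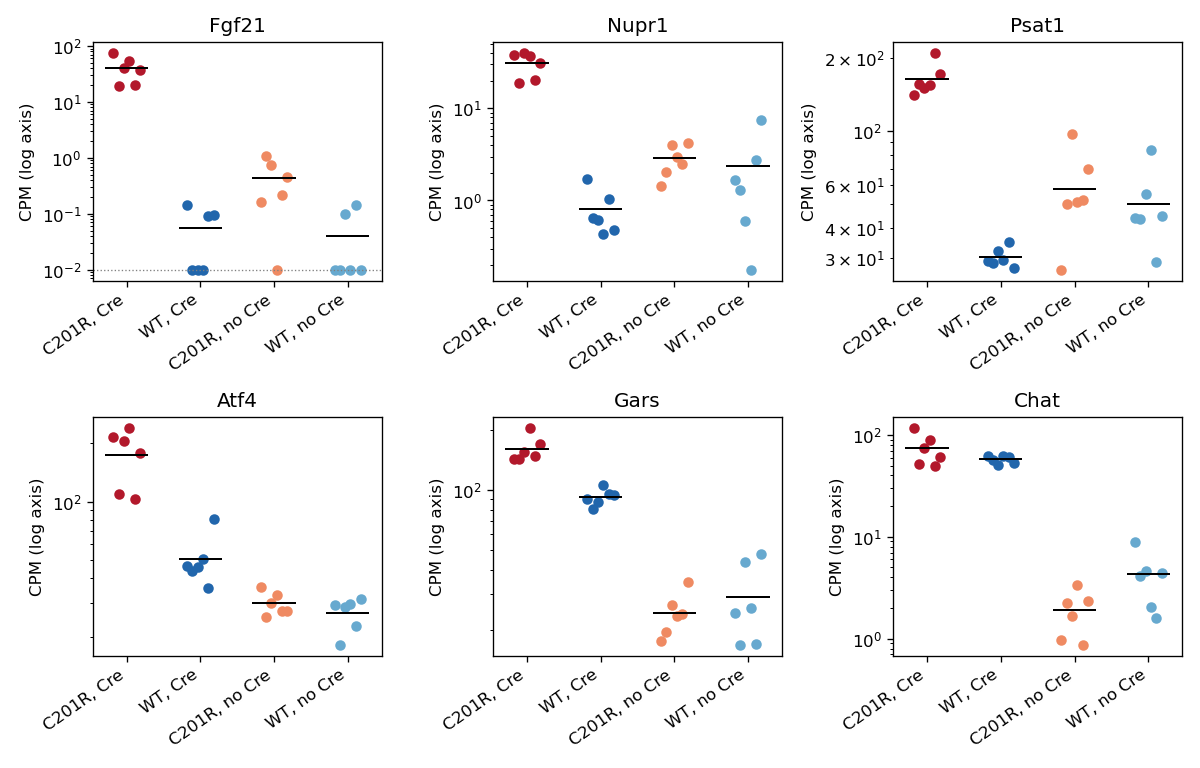
CPM on log axes for Fgf21, Nupr1, Psat1, Atf4, Gars and Chat, one point per library in 4 groups, with lines at group means of 6 libraries. Libraries with 0 counts of Fgf21 are drawn at the dotted line. C201R libraries with Cre lie above wild-type libraries with Cre for Fgf21, Nupr1, Psat1, Atf4 and Gars, and the groups overlap for Chat.

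Of 24 measured cytosolic aminoacyl-tRNA synthetases, which charge tRNAs for translation in the cytosol, 13 were higher (14 adjusted over the list alone), 0 were lower and 11 did not pass the test, with a median of 0.62. Camera called the list (adjusted p = 6.9e-17), and the call was lost at adjusted p = 0.062 with an estimated correlation. Wars was higher by 1.19 ± 0.12, Rars by 1.05 ± 0.13, Cars by 1.32 ± 0.18 and the mutated gene Gars by 0.80 ± 0.12 (adjusted p = 0.0020). With mouse number prefix as a replicate block, Gars had an adjusted p of 0.055. None of the 17 mitochondrial synthetases was called (median 0.16). Of 20 endoplasmic reticulum chaperone and unfolded protein response genes 2 were higher, Xbp1 by 0.63 ± 0.13 and Hsp90b1 by 0.60 ± 0.16, and the list's call was lost with an estimated correlation (adjusted p = 0.14). Chat and Rpl22, the marker and the tagged gene, had changes of 0.24 ± 0.17 and 0.25 ± 0.17 (adjusted p = 0.51 and 0.46).

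Alpha motor neurons drive the force-producing muscle fibres, and 10 of their markers were measured. In the pooled Cre enrichment 8 of the 10 were higher with Cre and 2 were lower, so not all were enriched in these pulldowns. Between genotypes with Cre, 4 were lower in C201R, 0 were higher and 6 did not pass the test, with a median of -0.73. Camera called the list (adjusted p = 1.2e-06), and the call was lost at adjusted p = 0.14 with an estimated correlation. Calca changed by -1.47 ± 0.24, Rbfox3 by -1.12 ± 0.24, Chodl by -1.02 ± 0.14 and Kcnq5 by -0.98 ± 0.20. Over the alternatives the adjusted p with an estimated correlation ranged from 0.032 without mice 14003-1 and 14701-9, the only fit of those run in which it passed, to 0.24 with mouse number prefix as a replicate block. With the Gm26924 share as a covariate the alpha median was -0.47. Of the 16 cholinergic markers, some of which are also alpha markers, 4 were lower (Chodl, Ahnak2, Calca and Calcb; adjusted p = 0.50 with an estimated correlation), and the list median of -0.15 was -0.05 with the block and -0.02 with the Gm26924 share as a covariate. None of the 10 gamma motor neuron markers was called (median -0.16). The gene with the smallest p among lower genes was Cd24a, a surface glycoprotein gene, at 363 ± 72 CPM in C201R and 1311 ± 207 CPM in wild type. Pex5l, Cd55, Ano3, Mtus2, Dclk1, Mest, Tmod1, Sphkap, Slitrk4 and Hecw1 were also among the 12 lower genes named by the rule.

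Of 23 voltage-gated channel genes 5 were lower and 1 higher, among them Cacna1a (-0.94 ± 0.18) against Scn2b (0.78 ± 0.14; list adjusted p = 0.34 with an estimated correlation). The list median of -0.42 was -0.21 with the prefix block, -0.22 with the Gm26924 share as a covariate and -0.26 in series 2. Of 15 heat shock and ubiquitin stress genes 5 were higher, including the mitochondrial chaperonin Hspe1 (1.59 ± 0.15), Hsph1 (0.76 ± 0.12) and Hspa8 (0.73 ± 0.17). Of 11 p53 targets and apoptosis genes 3 were higher, with the cell cycle inhibitor Cdkn1a at 2.60 ± 0.30. The p53 list median of 0.72 turned to -0.008 in series 2, and was 0.43 with the prefix block, 0.36 with the Gm26924 covariate and 0.32 without mice 14003-1 and 14701-9. Both the heat shock and the p53 lists lost their call with an estimated correlation (adjusted p = 0.14 each). Of 80 cytosolic ribosomal protein genes 10 were higher (50 adjusted over the list alone), with a median of 0.52, and of 75 oxidative phosphorylation genes 8 were higher, with a median of 0.44 (adjusted p = 0.30 and 0.39 with an estimated correlation). With the Gm26924 covariate the medians were 0.32 and 0.15, with the prefix block 0.31 and 0.21, and in series 2 they were 0.29 and 0.26. Neither the 12 oligodendrocyte markers (median -0.18) nor the 12 endothelial and mural markers (median -0.03) held a called gene. Of the 7 blood cell markers 0 were called, with a median of 1.08 (adjusted p = 0.40 with an estimated correlation) that was 0.26 with the Gm26924 covariate. Camera also called the 14 markers of other spinal neurons (median 0.34) and 4 markers of dorsal root ganglion sensory neurons (median 1.39), with 0 called members each, and lost both calls with an estimated correlation (adjusted p = 0.40 and 0.30). With the prefix block the median of other spinal neurons was 0.20. The lists not called by camera held 1 higher astrocyte gene of 12, 1 lower fibroblast, meningeal and Schwann gene of 10, 1 lower mTORC1 and autophagy gene of 18, 3 higher injury genes of 17, and 2 higher and 2 lower neurofilament and transport genes of 20. The lists of oligodendrocyte precursors, microglia, synaptic vesicles, cholesterol synthesis, interferon-stimulated genes and immediate early genes held 0 called genes.

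**Figure D3:**
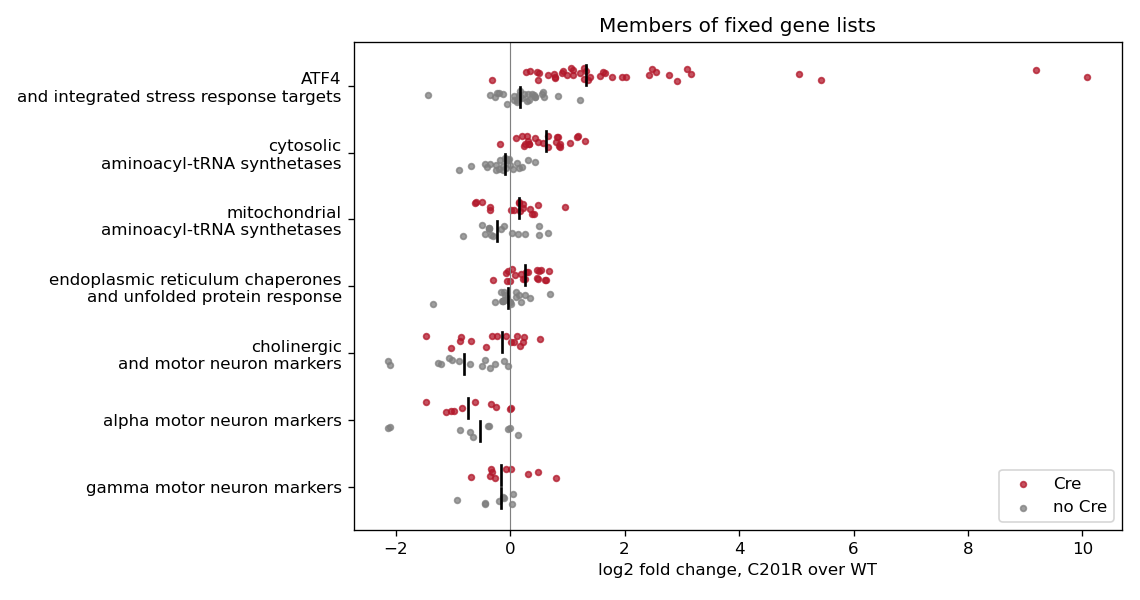
Log2 fold change of C201R over wild type for each measured member of 7 gene lists fixed in advance, in pulldowns with Cre (red) and without Cre (grey), with black bars at list medians. The ATF4 list has a median of 1.33 with Cre and 0.17 without Cre.

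In all, 601 of 14634 genes were called between the genotypes with Cre, 335 higher and 266 lower in C201R. The number depended on the libraries and the model. For the genotype effect in Cre-positive pulldowns it was 1370 in series 2 alone (3 against 4 libraries) and 1 in series 1 alone (3 against 2), and 75 with mouse number prefix as a replicate block. Without mice 14003-1 and 14701-9 it was 1950. With library totals the median of all genes moved from -0.006 to -0.26, and 32 genes were called.

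Without Cre, 0 of 14400 genes were called between the genotypes by edgeR, with 455 at an unadjusted p under 0.05, while DESeq2 called 2 and limma-voom 1. The ATF4 list had a median of 0.17 over 30 measured members (adjusted p = 0.032 with an estimated correlation). Cholinergic markers had a median of -0.80 over 14 members (adjusted p = 0.040 with an estimated correlation) and alpha markers of -0.52 over 10 (adjusted p = 0.032). The cholinergic list level was 2.88 ± 0.33 log2(CPM+1) in C201R and 3.86 ± 0.49 in wild type without Cre (SD, n = 6; exact two-sided permutation p = 0.0043, adjusted p = 0.0087; within library series, adjusted p = 0.016), and 6.15 ± 0.247 and 6.37 ± 0.255 with Cre (exact permutation p = 0.17, adjusted p = 0.26). Chat had a change of -1.20 ± 0.52 (adjusted p = 1.00) and Gars of -0.24 ± 0.24.

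The genotype by Cre interaction tested whether the genotype change with Cre differed from that without it. It called 21 of 16109 genes, 16 with a more positive and 5 with a more negative change with Cre. The ATF4 list had a median interaction of 1.02 with 6 of 39 members called (adjusted p = 7.6e-09 with an estimated correlation). The called members included Psph (2.90 ± 0.35), Psat1 (2.31 ± 0.31), Nupr1 (4.84 ± 0.74) and Atf4 (1.57 ± 0.28). The cytosolic synthetase list had a median of 0.84 (adjusted p = 0.023 with an estimated correlation) with Rars called at 1.30 ± 0.24. The alpha list had a median of 0.01 with 0 called members, so a genotype difference specific to pulldowns with Cre was not shown for it. Gars had an interaction of 1.10 ± 0.31 (adjusted p = 0.20).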

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

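The tests of ribosomal RNA, other cells and library series for the ATF4 list were chosen after its rise was seen, as were the fit without mice 14003-1 and 14701-9, the Gm26924 covariate and the bootstrap bounds in their tests for the alpha and ribosomal protein lists. Single libraries were compared with the other 5 of their group by Dixon's criterion for 62 sets of values, of which 14 passed. For normal values chance passes about 1 in 20. CPM values were used here without a log transform, and many sets come from the same libraries, so the 14 cannot be set against that rate. C201R mouse 14003-1 with Cre had 12.1 M counts and 15.8% mitochondrial transcripts. Wild-type mouse 14701-9 with Cre had 17.1% mitochondrial transcripts, 30.8% Gm26924, a cholinergic list median of 5.87 log2(CPM+1), Atf4 at 80.8 CPM and Cd24a at 751 CPM. Among pulldowns without Cre, C201R mouse 14003-2 had 7.60% Gm26924 and Adm2 at 1.93 CPM, C201R mouse 14004-8 had 35.2% mitochondrial transcripts, and C201R mouse 14003-3 had Pex5l at 119 CPM. Wild-type mouse 14702-5 had 9.14 M counts, and wild-type mouse 14702-6 had Nupr1 at 7.55 CPM and Cd24a at 222.0 CPM.

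The genotype change differed between pulldowns with and without Cre for 21 genes by the interaction test. The values on the log2 scale were 2.90 for Psph, 2.37 for Cyb5r1, 1.92 for Clic4, 2.31 for Psat1, 4.84 for Nupr1, 2.66 for Arhgef2, 1.57 for Atf4, 2.54 for Atf5, 1.30 for Rars, 3.26 for Phgdh, 1.42 for Hnrnpa2b1 and 1.31 for Hnrnph1. They were -1.11 for Pex5l, -1.14 for Dclk1, -4.57 for Srp54a, -1.12 for Zhx3 and -1.44 for Ano3. The other 4 genes, all with a positive interaction, fall outside the rule for named genes. Of 80 arrangements of the genotype labels within the Cre groups, 2 gave at least 21 genes, the real one included. So high a count was rare, but it also arose from an arrangement that mixes the genotypes. The count alone therefore does not exclude chance. The highest other arrangement called 299 genes, many times the real count, while the median over the other arrangements was 0. That highest arrangement placed mice 14003-1 and 14701-9 in the same group. These mice had the highest mitochondrial shares with Cre, and their deviations from their groups correlated at 0.435 across genes. Random arrangements often place any 2 given mice together, so this placement does not show why the count was high. Whether these mice account for the count was not tested.

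For the other comparisons, 1 of 100 splits of the libraries gave as many genes as the 601 between genotypes with Cre, which was the real one, and the highest other split gave 1. Without Cre the real count is 0, which all 100 splits reach by construction, so the splits say nothing there; the highest gave 5. For Cre enrichment only the real split of 100 reached 8637 genes in wild type and 8145 in C201R, against 4208 and 4788 in the highest others. In the pooled enrichment only the real arrangement of 80 reached 11401 genes, against 5745.

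The ATF4 list was higher in C201R pulldowns with Cre, with a median of 1.33. If a greater share of ribosomal RNA were the whole cause, adjusting for the Gm26924 share should have removed most of the rise, but the median stayed at 1.30. RNA of other cells would raise the list as much without Cre, but the median interaction was 1.02. Library series alone is argued against by a median of 1.30 within series 2. A response of the tagged cells to the mutation remains as a hypothesis, and was found and tested on the same data.

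Of 10 alpha motor neuron markers 4 were lower, with a list median of -0.73 that was not called with an estimated correlation (adjusted p = 0.14). A smaller share of cholinergic RNA would lower other enriched genes by a similar amount. The 100 genes with the highest pooled Cre enrichment, alpha list left out, fell less, with a median of -0.20 (95% bootstrap interval -0.29 to 0.006). The interval takes genes as independent and leaves out the spread between mice, and the ranking used the C201R pulldowns too. A smaller cholinergic share as the whole cause is thus made less likely but not excluded. With the Gm26924 share as a covariate the alpha median was -0.47, with a 95% bootstrap interval of -0.92 to -0.07 that holds both the whole and a small part of the change, so a part played by ribosomal RNA cannot be told apart from one of genotype. Without Cre the alpha list had a median of -0.52 (camera adjusted p = 0.032 with an estimated correlation), and its median interaction was 0.01. A genotype difference shared with the background pulldowns was therefore not argued against for this list. Fewer alpha motor neurons and less of these transcripts per cell were not tested.

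Of 80 ribosomal protein genes 10 were higher, with a list median of 0.52 that was not called with an estimated correlation (adjusted p = 0.30). Genes outside the list matched on length and expression had a median of 0.36 (95% interval 0.27 to 0.43), which is consistent with a general rise of short transcripts; the list's median length was 728 bases against 2520 for all genes tested. Without mice 14003-1 and 14701-9 the median was 0.46 (95% bootstrap interval 0.38 to 0.56), so it depended little on these libraries. The interval takes the members as independent, though their estimated correlation over all 12 libraries was 0.494, and leaves out the spread between mice. By camera with an estimated correlation the list was not called in this fit either (adjusted p = 0.415). The list median of 0.52 lies above the interval of the matched genes, but that interval covers only the draw of genes and not the spread between mice. Whether ribosomal protein genes rose beyond other transcripts of their length and expression was therefore not decided.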

How the results depend on the processing

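List fits in series 2 alone and alternatives with library totals, with mitochondrial rows and Gm26924 removed, with the Gm26924 share as a covariate and without mice 14003-1 and 14701-9 were chosen after seeing the data. The genotype effect in Cre-positive pulldowns had the least stable count: 601 became 291 without the series term, 32 with library totals, 1950 without both mice, 1344 with DESeq2, 278 with limma-voom, 1370 in series 2 alone, 1 in series 1 alone, 335 with Xist as a covariate, 178 in a fit of all 24 libraries, 204 with the oligodendrocyte and 114 with the Gm26924 covariate. With mouse number prefix as a replicate block, which takes some libraries out of the genotype contrast, it was 75. The 6 pairs of libraries in different groups that share a prefix had correlations of deviations from -0.02 to 0.40 (median 0.114). For 30 pairs in different groups with different prefixes the range was -0.517 to 0.435 (median 0.029). The 6 pairs are few and also share a library series, so whether the prefixes pair the libraries was not decided. The cause of the lower count with the block was not tested.

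For the genotype effect in Cre-positive pulldowns no called gene changed direction in these fits. The share of higher genes rose from 55.7% to 75% with library totals and 80% with the block, and fell to 40% in series 2. Leaving out 1 library gave 170 (C201R 14703-4) to 936 (C201R 14003-1) genes, with 395 without C201R 14004-2, 380 without C201R 14003-4, and 219, 313, 253, 349 and 246 without wild-type 14002-6, 14004-6, 14702-3, 14703-5 and 14004-3. Of 62 named genes called, 1 kept its call in series 1 alone, 15 with library totals, 27 with the block and 32 in the fit of all 24 libraries.

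For the genotype effect in no-Cre pulldowns, 0 genes became 2 with DESeq2, 1 with limma-voom, 6 without a filter, 1 with the replicate block and 2 in the fit of all 24 libraries, and stayed at 0 to 0 with each library left out. The genotype by Cre interaction gave 1 gene with library totals, 43 without both mice, 115 with DESeq2, 42 with limma-voom and 6 with the block, and 11 to 37 with 1 library left out (37 without wild-type 14701-1, 34 without wild-type 14701-9, and 11 to 13 without C201R 14003-3, 14702-8 or 14703-4 or wild-type 14002-6, 14004-6, 14702-3, 14004-4 or 14004-3). Counts for Cre enrichment in wild type stayed within 1.5 times of 8637 (7912 to 9378 with 1 library left out) and those for Cre enrichment in C201R of 8145 (7067 to 9323), but there the majority turned from higher (4370 against 3775) to lower (3784 against 4381) with RLE scaling.

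Of 28 lists, 13 were called between genotypes with Cre, 1 with an estimated correlation and 7 by fry. The ATF4 median ranged from 1.29 without both mice to 1.51 without the series term, called in every fit run. Of the 13 lists, medians shrank by over 1.5 times for 6 with the replicate block, 7 with the Gm26924 covariate, 1 without both mice (p53, to 0.32) and 3 in series 2, where the p53 list turned to -0.008. The injury list had -0.11 in series 2.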

Other observations

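The exact tests of Fgf21, Chat and Adm2 without Cre were chosen after their values were seen. Fgf21 stood in C201R pulldowns without Cre at 0.444 ± 0.408 CPM (SD, n = 6) against 0.041 ± 0.065 CPM in wild type without Cre (scaled over all 24 libraries; exact two-sided permutation p = 0.019, unadjusted, and 0.028 within library series). These values lie near the floor, ranging from 0 to 1.08 CPM in C201R and from 0 to 0.146 CPM in wild type, so the test rests on few counts. On the same scaling Chat had 1.91 ± 0.93 CPM in C201R and 4.29 ± 2.60 CPM in wild type without Cre (exact permutation p = 0.037, unadjusted, and 0.060 within library series). The tests are 2 of 3 run on single genes without Cre; the third, on Adm2, gave an exact permutation p of 0.061 and 0.083 within library series.

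Cox6a2, a subunit of cytochrome oxidase known from striated muscle, had the highest change of the oxidative phosphorylation list with Cre, at 6.55 ± 0.86 on the log2 scale (SE, adjusted p = 0.00075), with 11.1 ± 9.2 CPM in C201R and 0.205 ± 0.471 CPM in wild type. Srp54a, which encodes a subunit of the signal recognition particle, stood at 20.6 ± 6.2 CPM in C201R and 17.1 ± 3.8 CPM in wild type with Cre (SD, n = 6). Without Cre it stood at 3.54 ± 3.16 CPM in C201R and 0.107 ± 0.174 CPM in wild type. The wild-type libraries without Cre held 8 counts of Srp54a in all, so its negative interaction rests on few counts. Of the injury list, Gadd45a was higher in C201R with Cre by 1.12 ± 0.18, Gap43 by 0.69 ± 0.17 and Adcyap1 by 0.85 ± 0.22, 3 of 17 measured members, and the list itself was not called (adjusted p = 0.34 with an estimated correlation).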
